A study of Homo sapiens with 6 samples.

How the data were processed

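Total RNA from cultured BJ cells, an established human skin fibroblast line with a limited replicative lifespan, was sequenced as 6 libraries: 3 from early cells at population doubling 15 and 3 from senescent cells at population doubling 44. Per the labels' protocols, ribosomal RNA was depleted with a stranded kit, the reads were paired, and the replicates were biological. The labels do not say whether the replicates came from separately passaged cultures, so p-values measure the spread between these 3 samples a group. Groups were taken from the population doubling in the labels and replicate numbers from the sample titles.

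Each library has 1 deposited table with 195584 transcripts. Per the file headers and the submitters' processing notes, the authors made these tables with kallisto, which assigns reads to transcripts without a genome alignment. They hold the estimated count, the TPM (transcript abundance scaled to a common total within the library, computed by the authors' run of the tool), the length and the effective length of each transcript. The version, index and options are not given in the sources used here. The tables carry no bootstrap estimates, so the uncertainty of splitting reads among isoforms of a gene is unknown. The submitters' processing notes also name STAR, Picard, sleuth, featureCounts and DESeq2, without a role, and the build hg19.

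A further deposited table of the whole series holds the authors' own DESeq2 comparison for 57445 genes, with gene coordinates in hg19 used as given. Per the file headers, its columns are a mean normalised count over the libraries (a signal averaged by the authors), a log2 fold change, its standard error and Wald score, a p-value and an adjusted p-value. No header states the direction of the fold. The name of the deposited table places early over senescent, so the sign was turned here to read senescent over early, and the turned folds were checked against those of the transcript tables. Its values are always named as the authors'. How reads were counted for it, including the use of strand, is not given in the sources used here.

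Transcripts were matched to genes by stable Ensembl identifier through GENCODE release 29. That annotation is on build GRCh38 and served only for gene names, gene types, transcript length, GC content and exon overlap. Of the transcripts, 92.3% matched, and these carried 95.7% to 96.2% of the estimated counts per library. The unmatched 3.82% to 4.26% entered no gene test, so a gene whose transcripts were retired or renumbered is low or missing here. Estimated counts were summed per gene and rounded to whole numbers. Near-identical copies, such as histone genes, metallothioneins, ribosomal protein genes and their pseudogenes, share reads that kallisto divides by estimate, and their values are uncertain for that reason.

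The libraries held 23500291 to 35557509 estimated counts. Mitochondrially encoded genes took 0.23% to 0.785% of gene counts and small structured RNA genes 0.235% to 1.12%, and the 10 most counted genes took 11.3% to 12.5%. Reads carry no molecular identifiers, so intervals made from counts cover counting error only.

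Genes were tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood F-test, with TMM scaling, the default expression filter and the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all 16029 genes that passed the filter, and 0.05 was the threshold. Log2 folds are senescent over early, with a standard error equal to the fold divided by the square root of F. Counts scaled to a common library total (CPM) use the same factors and are given as mean ± SD over 3 libraries. The same test was run on the rounded estimated counts of 47083 transcripts. All adjusted p-values of genes and transcripts are from this edgeR test unless another tool is named.

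Before the data were examined, 35 gene lists were written from textbook knowledge: cell cycle, chromatin, secreted factors of senescent cells, 9 groups of lipid metabolism, organelles, stress responses and markers of cell types. The 31 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation between genes of 0.01, adjusted over lists). Camera with an estimated correlation and fry were run beside it. Of the 829 list entries, 820 matched a gene. The gene naming rule was also fixed then. It took the 8 largest rises and 8 largest falls among called genes with non-overlapping groups and a mean of at least 5 TPM in the higher group. It took for each list the 2 members with the smallest p and the leading member going the other way, together with 23 genes of senescence and lipid metabolism. Not every gene that the rule took is reported. Other members named beside a list were picked after their values were seen, to show its range.

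On counts simulated from these libraries, the gene test over 16029 genes recovered 65.7% of genes changed 1.5-fold, 97% of those changed 2-fold and 98.5% of those changed 4-fold, and 9.24% of its calls were false. The transcript test over 47083 transcripts recovered 1.49%, 19.4% and 54.5% of those sizes. Both shifted lists were called and 0 of 29 others. The simulated genes were drawn independently, so these list results do not test the preset correlation of 0.01. On the real data the correlation was estimated at 0.61 for ribosomal proteins and 0.46 for lysosome genes, the 2 shifted lists. The simulation changed 200 drawn genes and those lists, a far smaller share than the 39% called on the real data. Its share of false calls holds for that setting. Alternatives comprised other scalings and filters, offsets for effective length, a replicate block, each library left out, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), limma-voom, thinned counts, a minimum fold of 1.5 and the authors' deposited table. Gene length, GC content and read depth were not corrected in the reported values. Sequencing reads were not analysed here.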

Results

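RNA abundance was measured in 6 libraries of BJ cells, a human skin fibroblast line that stops dividing after a limited number of population doublings. Early cells, at population doubling 15, gave 3 libraries with 27203060, 33236585 and 28965704 estimated counts for replicates 1 to 3. Senescent cells, at population doubling 44, gave 3 libraries with 23500291, 29201176 and 35557509. The 1 comparison of the design asked which genes, gene groups and transcripts differed between the states, and the study's title places it in the regulation of lipids. Every fold is senescent over early, values are mean ± SD over 3 libraries a group, and coordinates are on hg19.

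Senescent cells differed from early cells across a large part of the transcriptome. Genes of mitosis were lower throughout, CXCL12, IGF2 and GFRA1 were among the deepest falls, and SYT1, PCDH10 and the fatty acid receptor CD36 were among the steepest rises, of genes with at least 5 TPM in the higher group. Of 16029 genes tested, 6254 passed (39%), 2883 higher and 3371 lower in senescent cells. A change of more than 2-fold was found for 615 of the higher and 895 of the lower genes. Protein-coding genes made up 5877 of the calls and long non-coding genes 296. The first principal component carried 64.6% of the variance and separated the groups. The share of calls that were higher was 46.1% here, 37.7% with library totals and 60.7% in limma on log2(TPM + 1), where both the test and the scale differ. In that limma run the median log2 fold of all genes was shifted by 0.12.

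**Figure D1:**
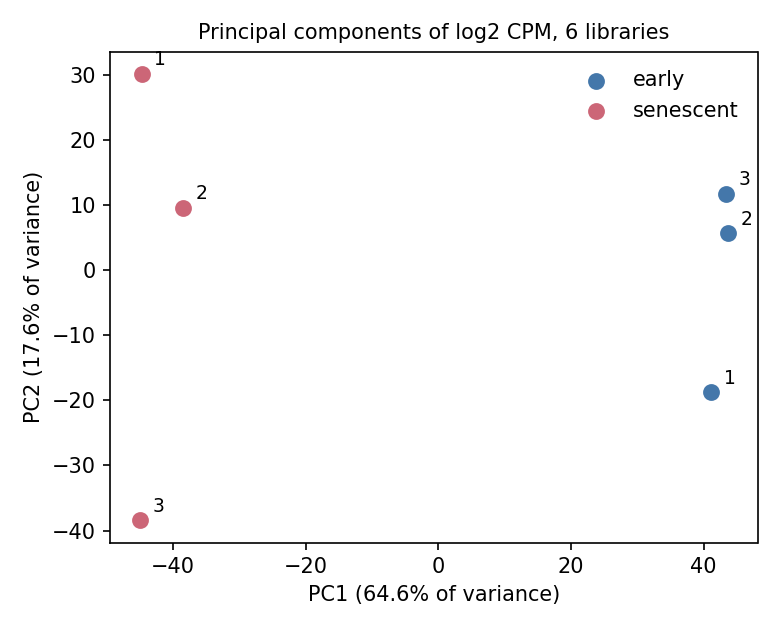
Principal components of log2 CPM, with 1 point per library, blue for early and red for senescent. Component 1 (64.6% of the variance) parts the groups, and component 2 (17.6%) spreads libraries within each group.

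Among the 8 steepest rises at that level, the membrane trafficking gene SYT1 (ENSG00000067715, 12:79257773 to 79845788), which encodes a calcium sensor of vesicle fusion, went from 3.20 ± 0.277 to 85.7 ± 6.17 CPM (log2 fold 4.74, SE 0.0995, n = 3 per group, edgeR adjusted p = 5.7e-12). The cell adhesion gene PCDH10 (ENSG00000138650, 4:134070470 to 134129356), a protocadherin, rose from 33.7 ± 4.17 to 477 ± 28.6 CPM (log2 fold 3.82, SE 0.10, n = 3, edgeR adjusted p = 4e-11). SLITRK6 rose 51.5-fold from a low early level of 0.386 CPM, and RXFP1, the relaxin receptor, rose 20.9-fold. The urea transporter gene SLC14A1 rose 18.6-fold and PLEKHH2 rose 11.1-fold. For SLC14A1 the log2 fold was 4.21 here and 5.40 in the authors' deposited table.

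Among the 8 deepest falls at that level, GFRA1 (ENSG00000151892, 10:117816444 to 118032979), a receptor for glial cell line-derived neurotrophic factor, went from 114 ± 6.14 to 5.10 ± 0.425 CPM (log2 fold -4.47, SE 0.0903, n = 3, edgeR adjusted p = 5.7e-12). The chemokine gene CXCL12 (ENSG00000107562, 10:44793038 to 44881941) went from 209 ± 22.1 to 11.7 ± 2.13 CPM (log2 fold -4.15, SE 0.14, n = 3, edgeR adjusted p = 1.6e-08). The growth factor gene IGF2 was 13.4-fold lower, at 65.4 ± 9.38 against 879 ± 130 CPM. VAT1L was 19.2-fold, the non-coding LINC00578 14.2-fold and the stress kinase gene MAP2K6 11.5-fold lower. Senescent libraries held 1 to 7 counts of the metallothionein gene MT1F, 24.6 times fewer than early ones after scaling for depth (95% exact binomial interval 14.2 to 46.7). They held 3 to 7 counts of TRBC2, a T cell receptor constant gene with a near-identical neighbour, 13.6 times fewer (7.75 to 26). The authors' deposited table gave smaller falls for both, with log2 folds of -3.75 for MT1F and -2.73 for TRBC2, against -4.57 and -3.73 here.

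**Figure D2:**
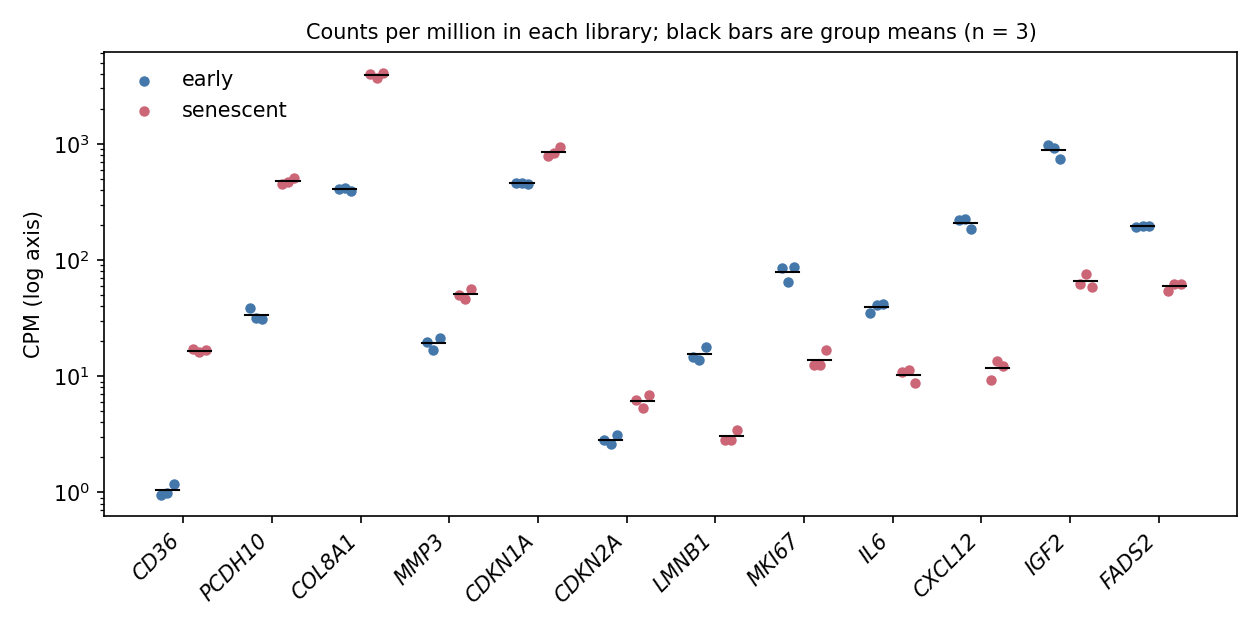
CPM on a log axis for 12 named genes, with 1 point per library, blue for early and red for senescent, and black bars for means of 3 libraries. CD36 went from 1.04 to 16.6 CPM and CXCL12 from 209 to 11.7 CPM.

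Genes of mitosis fell together. All 32 tested mitosis and G2/M genes fell, with a median log2 fold of -2.16, and 32 fell adjusted over the list alone (camera adjusted p = 4.73e-20, and adjusted p = 0.728 with an estimated correlation). DLGAP5, a spindle protein gene, fell to 1.94 ± 0.161 from 13.9 ± 1.16 CPM (log2 fold -2.83, n = 3). The proliferation marker MKI67 was 5.63-fold lower (edgeR adjusted p = 1.1e-05) and the cytokinesis gene ANLN 4-fold lower. Of 37 DNA replication and G1/S genes, 19 fell, 1 rose and 17 did not pass (1 rose and 21 fell adjusted over the list alone). Their median log2 fold was -0.37 (camera adjusted p = 0.000153, and adjusted p = 0.728 with an estimated correlation). The nucleotide synthesis genes TK1 and RRM2 had log2 folds of -2.48 and -2.02. The single riser, the DNA polymerase subunit gene POLA2 (log2 fold 0.34, edgeR adjusted p = 0.041), lost its call in 12 of the alternatives, among them the runs without senescent replicate 3 (0.22, adjusted p 0.159) and without early replicate 1, 2 or 3 (0.32, 0.31 and 0.35).

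Of 12 tested replication-dependent histone genes, out of 18 fixed and 13 matched, 8 fell and 4 did not pass, and 9 fell adjusted over the list alone. The list's median log2 fold was -0.82 (camera adjusted p = 0.000978, and adjusted p = 0.728 with an estimated correlation). HIST1H1B, a linker histone gene, had a log2 fold of -2.72 and HIST1H3H one of -1.57, while HIST1H1C stood at 0.01. Near-identical histone copies share reads. Of 26 nuclear lamina and chromatin genes, 14 fell, 1 rose and 11 did not pass, with the same counts adjusted over the list alone. At the median, their log2 fold was -0.29 (camera adjusted p = 0.0023, and adjusted p = 0.728 with an estimated correlation). LMNB1, a lamina gene whose loss is a common marker of senescence, went from 15.5 ± 2.13 to 3.04 ± 0.367 CPM (log2 fold -2.34, n = 3, edgeR adjusted p = 2.2e-08). TMPO and HMGB2 fell by 1.00 and 1.02 on the log2 scale. The riser, the polycomb gene EED (0.28, edgeR adjusted p = 0.032), lost its call in 13 alternatives, among them the runs without senescent replicate 2 (0.28) or 3 (0.22) and without early replicate 1, 2 or 3 (0.29, 0.23 and 0.29). Of 28 DNA repair genes, 15 fell, 4 rose and 9 did not pass, again with the same counts adjusted over the list alone. The median member had a log2 fold of -0.56 (camera adjusted p = 0.00478, and adjusted p = 0.728 with an estimated correlation). The checkpoint kinase genes CHEK1 and ATR went opposite ways, at -1.23 and 0.42, and the helicase gene BRIP1 stood at -0.98. With offsets for effective length the list's median was -0.34 and its call was lost (adjusted p = 0.14), as was that of BRIP1 (-0.83, adjusted p = 0.0595).

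Genes of the senescence checkpoint list were higher in the majority. Of 24 tested, 14 rose, 4 fell and 6 did not pass, with the same counts adjusted over the list alone. Members had a median log2 fold of 0.39 (camera adjusted p = 0.0023, and adjusted p = 0.728 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 455 ± 4.87 to 849 ± 77.1 CPM (log2 fold 0.90, SE 0.0805, n = 3, edgeR adjusted p = 1.3e-06). GADD45A rose by a log2 fold of 1.29 and CDKN2B by 0.55. CDKN1B fell by 0.67 on the log2 scale. CDKN2A (ENSG00000147889, 9:21967751 to 21995300) rose from 2.85 ± 0.255 to 6.13 ± 0.758 CPM (log2 fold 1.11, SE 0.149, n = 3, edgeR adjusted p = 5.6e-05). Its transcript ENST00000304494, of the kind that encodes the inhibitor p16INK4a, rose from 1.69 ± 0.462 to 8.17 ± 2.34 TPM (log2 fold 2.14, SE 0.247, n = 3, edgeR adjusted p = 0.0032). Its transcript ENST00000579755, with the distant start used for ARF, stood at 1.30 ± 0.550 and 0.259 ± 0.449 TPM and did not pass (log2 fold -2.38, SE 1.4, edgeR adjusted p = 0.401). The authors' deposited table gave CDKN2A a log2 fold of 0.07 (DESeq2 adjusted p = 0.739).

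Of the 2 lists of secreted factors linked to senescence, camera called 1, and the difference between the lists was not tested. Of 29 tested SASP proteases, inhibitors and growth factors, 18 rose, 5 fell and 6 did not pass (19 rose and 6 fell adjusted over the list alone). Their median log2 fold was 0.54 (camera adjusted p = 0.000522, and adjusted p = 0.728 with an estimated correlation). The growth factor gene EREG rose 7.69-fold, the protease inhibitor gene SERPINB2 6.45-fold and the stromelysin gene MMP3 2.65-fold, from 19.3 ± 2.36 to 51.1 ± 5.27 CPM. FGF7 was 4.29-fold lower. The collagenase gene MMP1 did not pass (log2 fold -0.21, edgeR adjusted p = 0.055), though it did without senescent replicate 3 (-0.26, adjusted p = 0.0239) and without early replicate 1 (-0.27, adjusted p = 0.0131). MMP1 also passed with library totals (adjusted p = 0.0133), with no filter (0.0398), with the CPM filter (0.0438) and among genes with comparable counts in the authors' table (0.0418), the last chosen after the data were seen. Of 24 SASP cytokines and chemokines, 10 had enough counts to test, of which 5 fell, 1 rose and 4 did not pass (2 rose and 5 fell adjusted over the list alone). The list had a median log2 fold of -0.45 and was not called (camera adjusted p = 0.138). The median was -0.27 without early replicate 3, and the list was called with no filter on low counts (median -0.43, adjusted p = 0.0182). The interleukin gene IL6 fell from 39.5 ± 3.87 to 10.3 ± 1.39 CPM (log2 fold -1.94, SE 0.11, n = 3, edgeR adjusted p = 2.3e-08). TNFRSF11B, a decoy receptor gene, rose by a log2 fold of 0.55. CXCL8 was too low to test, with 16 counts over the early and 15 over the senescent libraries.

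With all 6 libraries and the default filter camera called 0 of the 9 lipid lists, and lists of lipid metabolism held members that rose and members that fell. Fry gave a directional call to cholesterol efflux and LXR targets (adjusted p = 0.00819), fatty acid uptake (0.0289) and sphingolipid metabolism (0.0271). In fatty acid uptake, binding and activation, 5 of 19 tested genes rose, 6 fell and 8 did not pass, with the same counts adjusted over the list alone (median log2 fold 0.03, camera adjusted p = 0.908). CD36 (ENSG00000135218, 7:79998891 to 80308593), a scavenger receptor that takes up long-chain fatty acids, rose from 1.04 ± 0.126 to 16.6 ± 0.547 CPM (log2 fold 3.99, SE 0.129, n = 3, edgeR adjusted p = 2.1e-10). The caveolin gene CAV2 rose by a log2 fold of 0.89, and DBI, which encodes an acyl-CoA binding protein, fell by 1.00. In fatty acid synthesis, elongation and desaturation, 4 of 20 rose, 6 fell and 10 did not pass, with the same counts adjusted over the list alone. The list's median log2 fold was 0.0099, its mean was -0.27 and the test pointed down (camera adjusted p = 0.885). The desaturase gene FADS2 (ENSG00000134824, 11:61560452 to 61634826), which acts on polyunsaturated fatty acids, fell from 195 ± 3.20 to 59.6 ± 4.38 CPM (log2 fold -1.71, SE 0.0756, n = 3, edgeR adjusted p = 2.2e-09). The stearoyl-CoA desaturase genes SCD and SCD5 went opposite ways, with log2 folds of -0.70 and 0.88. FASN, the fatty acid synthase gene, did not pass (-0.12, edgeR adjusted p = 0.311).

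In triacylglycerol synthesis and lipid droplets, 4 of 22 tested genes rose, 5 fell and 13 did not pass, with the same counts adjusted over the list alone. The median log2 fold was 0.07 and the test pointed up, while the mean was -0.08 (camera adjusted p = 0.908). GPAT2, an acyltransferase gene, had a log2 fold of -1.80 and BSCL2, the seipin gene, one of 0.83. For BSCL2 the authors' deposited table gave -0.13 (DESeq2 adjusted p = 0.765). The droplet coat gene PLIN2 stood at 0.16 (edgeR adjusted p = 0.142) and passed without senescent replicate 1 (0.23, adjusted p = 0.0328), while without senescent replicate 3 it was 0.088. The adipogenic regulator gene PPARG stood at -0.38 (edgeR adjusted p = 0.0676), and passed with library totals (-0.44, adjusted p = 0.0432) and in the authors' deposited table (-0.38, DESeq2 adjusted p = 0.0443). In lipolysis and fatty acid oxidation, 4 of 34 rose, 10 fell and 20 did not pass (6 rose and 10 fell adjusted over the list alone), with a median log2 fold of -0.05 (camera adjusted p = 0.455). The carnitine carrier gene SLC25A20 rose by 0.72. PPARA, a regulator of fatty acid oxidation, fell by 0.74 on the log2 scale, the monoacylglycerol lipase gene MGLL fell by 0.64 and the carnitine palmitoyltransferase gene CPT1A fell by 0.47. The triglyceride lipase gene PNPLA2 stood at -0.02 (edgeR adjusted p = 0.889).

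In cholesterol synthesis and uptake, 4 of 25 tested genes rose, 5 fell and 16 did not pass, with the same counts adjusted over the list alone. The median log2 fold was 0.07 (0.0015 without senescent replicate 3, 0.12 without senescent replicate 2) and the test pointed up, while the mean was -0.06 (camera adjusted p = 0.908). MSMO1, a sterol oxidase gene, rose from 36.2 ± 5.53 to 57.2 ± 5.95 CPM (log2 fold 0.65, n = 3, edgeR adjusted p = 0.00084). In cholesterol efflux and LXR targets, 2 of 17 rose, 6 fell and 9 did not pass, with the same counts adjusted over the list alone (median log2 fold -0.14, camera adjusted p = 0.0812). The median was -0.34 without senescent replicate 2 and -0.31 without early replicate 1. That list passed without senescent replicate 3 (median -0.26, adjusted p = 0.0253) and with no filter on low counts (median -0.43, adjusted p = 0.00313). The lysosomal acid lipase gene LIPA was 3.07-fold lower and the lysosomal cholesterol carrier gene NPC2 2.18-fold higher. SREBF1, which encodes a regulator of lipid synthesis, fell by 0.79 on the log2 scale (edgeR adjusted p = 9.9e-06).

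In sphingolipid metabolism, 14 of 32 tested genes rose, 4 fell and 14 did not pass (14 rose and 5 fell adjusted over the list alone). The median log2 fold was 0.20 and the list was not called (camera adjusted p = 0.0832), though it passed without senescent replicate 1 (median 0.25, adjusted p = 0.0448). The acid sphingomyelinase gene SMPD1 rose from 69.7 ± 3.97 to 171 ± 24.7 CPM (log2 fold 1.30, n = 3, edgeR adjusted p = 4.5e-07). The ceramide synthase gene CERS6 rose 2.03-fold, and UGCG, of glucosylceramide synthesis, fell by 0.69 on the log2 scale. In glycerophospholipid synthesis and remodelling, 7 of 30 rose, 7 fell and 16 did not pass, with the same counts adjusted over the list alone (median log2 fold 0.00013, camera adjusted p = 0.885). The acyltransferase genes LPCAT2 and MBOAT2 stood at 0.81 and -0.65. In phospholipases and eicosanoids, 6 of 23 rose, 6 fell and 11 did not pass (7 rose and 8 fell adjusted over the list alone), with a median log2 fold of -0.13 (camera adjusted p = 0.952). PLA2G16 rose by a log2 fold of 0.87 and the reductase gene PTGR1 fell by 0.70. The cyclooxygenase gene PTGS2 did not pass (-0.20, edgeR adjusted p = 0.111), though it did without senescent replicate 1 (-0.29, adjusted p = 0.0134), and it stood at -0.10 without senescent replicate 2.

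Most tested lysosomal and immediate early genes rose in senescent cells. Of 32 tested lysosome genes, 19 rose, 5 fell and 8 did not pass (21 rose and 5 fell adjusted over the list alone). The list's median log2 fold was 0.39 (camera adjusted p = 0.000745, and adjusted p = 0.81 with an estimated correlation). IDS, a sulfatase gene, rose by 0.78 and the cathepsin gene CTSH fell by 1.37 on the log2 scale. GLB1, the source of senescence-associated beta-galactosidase, did not pass (0.17, edgeR adjusted p = 0.0886). GLB1 passed in the authors' deposited table (0.20, DESeq2 adjusted p = 0.039), with the CPM filter (0.17, adjusted p = 0.0431) and, in a run chosen after the data were seen, among genes with comparable counts there (0.18, adjusted p = 0.0387). Of 16 immediate early genes, 12 rose, 1 fell and 3 did not pass, with the same counts adjusted over the list alone. At the median, their log2 fold was 0.57 (camera adjusted p = 0.00059, and adjusted p = 0.728 with an estimated correlation). The transcription factor genes EGR2 and EGR1 rose 5.2-fold and 2.51-fold, and MYC fell by 0.30 on the log2 scale.

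Matrix and cytoskeletal genes went both ways. Of 34 tested extracellular matrix genes, 12 rose, 10 fell and 12 did not pass, with the same counts adjusted over the list alone. The median log2 fold was -0.03, while the mean was 0.02 and the test pointed up (camera adjusted p = 0.864). COL8A1 (ENSG00000144810, 3:99357319 to 99518070), a short-chain collagen gene, rose from 407 ± 11.6 to 3915 ± 204 CPM (log2 fold 3.27, SE 0.0794, n = 3, edgeR adjusted p = 2.4e-11). The fibrillin gene FBN2 was 7.62-fold lower. Of 20 contractile and cytoskeletal genes, 4 rose, 6 fell and 10 did not pass (4 rose and 7 fell adjusted over the list alone), with a median log2 fold of -0.03 (camera adjusted p = 0.908). The matricellular gene CTGF rose 4.12-fold and the smooth muscle actin gene ACTG2 was 4.51-fold lower.

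Most tested ribosomal protein genes fell. Of 34 tested, 27 fell and 7 did not pass, and 28 fell adjusted over the list alone. The median member had a log2 fold of -0.44 (camera adjusted p = 3.94e-07, and adjusted p = 0.728 with an estimated correlation), with RPSA at -0.86 and RPS2 at -0.78. Of 31 nuclear-encoded oxidative phosphorylation genes, 11 fell, 1 rose and 19 did not pass, with the same counts adjusted over the list alone. Members had a median log2 fold of -0.20 (camera adjusted p = 0.0217, and adjusted p = 0.822 with an estimated correlation). UQCRC1 and NDUFV2 fell by 0.51 and 0.50 on the log2 scale and COX6A1 rose by 0.31. For NDUFV2 the authors' deposited table gave -0.35 without a call (DESeq2 adjusted p = 0.501). That value rests on few reads, with a mean count of 36.3, while NDUFV2 had 52.6 CPM in early and 37.2 CPM in senescent cells here. The list's call was lost without senescent replicate 2 (adjusted p = 0.0883) and without early replicate 2 (0.0627). Of the 13 mitochondrially encoded mRNAs, 0 passed in edgeR, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. DESeq2 and limma-voom also called 0. Their median log2 fold was -0.08 (camera adjusted p = 0.908), with MT-ND6 at 0.42, MT-CO3 at -0.36 and MT-CO2 at -0.38. Their share of gene counts ranged within the groups, from 0.23% in senescent replicate 3 to 0.785% in senescent replicate 1, and the median difference between those libraries was 1.68 on the log2 scale. Without senescent replicate 3 MT-CO2 was -0.052, MT-CO3 was -0.048 and the list's median was 0.29, without early replicate 2 0.045 and without early replicate 3 0.095.

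The lists of antioxidant, unfolded protein, interferon and glycolysis genes were not called. Of 23 antioxidant and NRF2 targets, 9 rose, 6 fell and 8 did not pass (9 rose and 8 fell adjusted over the list alone). The median log2 fold was 0.07 and the test pointed up, while the mean was -0.02 (camera adjusted p = 0.888). HMOX1 and NQO1, of haem breakdown and quinone reduction, fell by 1.31 and 1.08 on the log2 scale, and MGST1 rose by 0.76. Of 20 unfolded protein response genes, 5 rose, 10 fell and 5 did not pass (5 rose and 12 fell adjusted over the list alone), with a median log2 fold of -0.25 (camera adjusted p = 0.141). That list was called with no filter on low counts (median -0.28, adjusted p = 0.0334). The amino acid stress genes ASNS and CHAC1 stood at -0.92 and -0.99 and the chaperone gene DNAJB9 at 0.70. Of 30 interferon response genes, 10 rose, 6 fell and 14 did not pass (13 rose and 6 fell adjusted over the list alone), with a median log2 fold of 0.25 (camera adjusted p = 0.0812). That list passed without early replicate 1 (median 0.34, adjusted p = 0.0187), and its median was 0.16 without early replicate 3. PSMB9 and GBP1 fell by 1.54 and 0.65 on the log2 scale, and HLA-C rose by 0.70. Of 21 glycolysis genes, 2 rose, 6 fell and 13 did not pass, with the same counts adjusted over the list alone (median log2 fold -0.04, camera adjusted p = 0.705). ENO1 fell by 0.59 on the log2 scale and HK2 rose by 0.42.

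**Figure D3:**
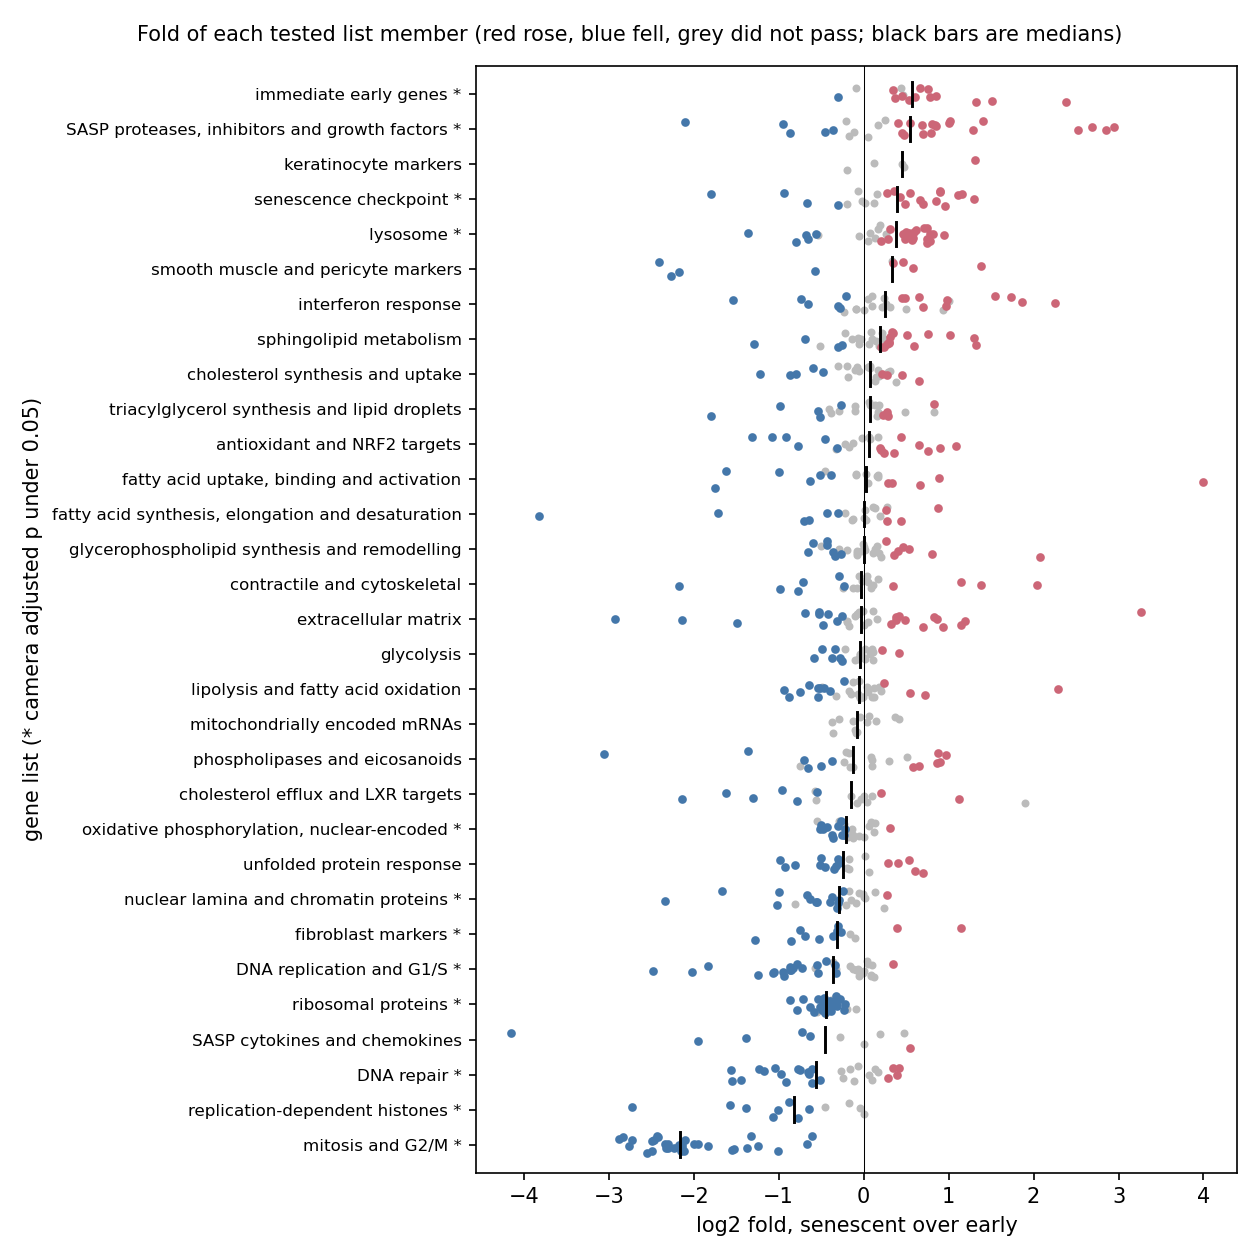
Log2 fold, senescent over early, of every tested member of the 31 tested lists, with 1 point per gene, red for rose, blue for fell, grey for did not pass and a black bar at each list's median. A star marks the 12 lists with a camera adjusted p under 0.05, from mitosis (median -2.16) to immediate early genes (median 0.57).

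Markers of fibroblasts were partly lower. Of 13 tested, 9 fell, 2 rose and 2 did not pass, with the same counts adjusted over the list alone. The list's median log2 fold was -0.31 (camera adjusted p = 0.032, and adjusted p = 0.81 with an estimated correlation). TWIST1 fell by 0.85 on the log2 scale and the proteoglycan gene LUM rose by 1.15. The call was lost without senescent replicate 1 (adjusted p = 0.0663), senescent replicate 2 (0.0669) and early replicate 2 (0.0517). Of 9 smooth muscle and pericyte markers, 4 rose, 4 fell and 1 did not pass, with the same counts adjusted over the list alone. The median log2 fold was 0.33, while the mean was -0.48 and the test pointed down (camera adjusted p = 0.908). MCAM was 4.83-fold lower. MYH11 was 2.61-fold higher, but lost its call with offsets for effective length (log2 fold 0.55, adjusted p = 0.194). Of 13 keratinocyte markers, 5 could be tested, of which DSP rose (log2 fold 1.31) and 4 did not pass, with the same counts adjusted over the list alone (median log2 fold 0.46, camera adjusted p = 0.214). That median was 0.27 without senescent replicate 1, 0.20 without senescent replicate 3 and 0.16 without early replicate 1. KRT10 stood at -0.19 and passed without senescent replicate 1 (-0.31, adjusted p = 0.0313), but was -0.069 without senescent replicate 3 and -0.13 without early replicate 2. Lists with fewer than 5 tested members had no set test, and the members named from them were chosen after their values were seen. The only testable endothelial marker, TEK, did not pass, with a log2 fold of -0.41. Of 4 leukocyte markers, PTPRC rose from 0.649 to 1.69 CPM, CD14 and CD68 fell and 1 did not pass, with the same counts adjusted over the list alone. Of 3 melanocyte and Schwann markers, MITF rose (log2 fold 0.62) and 2 did not pass, and of 4 adipocyte markers, LEP fell from 0.649 to 0.138 CPM and 3 did not pass (0 rose and 3 fell adjusted over the list alone).

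In all, camera called 12 lists, 4 higher and 8 lower. With an estimated correlation 0 were called, 1 having an unadjusted p under 0.05, and fry gave 18 lists a directional call. Fry did not call oxidative phosphorylation (adjusted p = 0.0908), and beyond the 3 lipid lists it called SASP cytokines (0.0032), the unfolded protein response (0.0271), keratinocyte markers (0.00153) and smooth muscle markers (0.00426), without comparing a list with other genes. Regrouping the libraries 3 against 3 in the other ways gave 1 to 11 list calls. Those groupings mix the states unequally, so they do not show how many lists would be called without a difference between states. Along the main axis of variation within groups, with senescent replicates 1 and 3 at its ends, several called lists stood far out among 2000 random lists. The ribosomal protein and oxidative phosphorylation lists were at percentile 100, histones at 99.8, SASP proteases at 0.1, immediate early genes at 0.55, lysosome at 0.85, fibroblast markers at 2.85 and mitosis at 3.55. These percentiles rank the lists and do not give the size of a difference. Among the 713 genes in tested lists, 166 rose and 255 fell. The counts were 172 and 245 with DESeq2 size factors and 153 and 298 with library totals, and 0 genes were called in opposite directions between scalings.

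Of 47083 transcripts tested, 4740 passed, 2380 higher and 2360 lower in senescent cells. Among the called transcripts, 274 belonged to tested genes that were not called, and 46 genes had called transcripts in each direction. The count was 2752 without senescent replicate 1, 2186 without senescent replicate 2, 3074 without early replicate 1, 2274 without early replicate 2 and 2580 without early replicate 3. The authors' deposited gene table had an adjusted p for 19584 genes, of which 6822 were called, 3446 higher and 3376 lower in senescent cells. Of 14677 genes tested in both, 5546 were called in both, 5544 of them in the same direction. Another 537 were called here only and 800 by the authors only. On the TPM scales, limma ended the calls of POLA2, EED, ATR, COX6A1, CPT1A, ENO1, MYC, MYH11 and NDUFV2 and those of HK2 on log2(TPM + 1) alone and MAP2K6 on log2(TPM + 0.1) alone. The correlation of log2 folds across the genes tested in both, which are not independent replicates, was 0.946 (Pearson).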

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

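The tests of this part were fixed before their results were seen.

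The authors' deposited table called 457 genes that were tested here under neither their identifier nor their symbol, 226 higher and 231 lower in senescent cells, and 240 of them are protein-coding. Genes whose symbol was tested under another identifier are not among them. This is signal in a part of the deposited data that the gene comparison did not use. No matched transcript was found for 115 of them, and 342 stayed under the count minimum here. A low count here need not mean low expression. SLC6A6, HIST1H2BK and LYNX1 had matched transcripts, and authors' mean counts of 10755, 2351 and 1280, while HIST1H2BK had 0 counts here. Histone genes made up 25, of which 24 were lower and 1 was higher. Examples chosen after their values were seen are the gap junction gene GJA5 (authors' log2 fold 3.56), TXNIP (1.92), which encodes an inhibitor of thioredoxin, the histone gene HIST1H3B (-2.74) and the mitotic gene FAM83D (-2.42).

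For 146 of the 14677 genes tested in both, the log2 fold here and in the authors' table differed by more than 1. Of these 89 were called here, 77 by the authors, and 2 in both with opposite signs. Counting of reads from the opposite strand is argued against as a general cause, since exons overlapped those of an opposite-strand gene for 41.8% of these genes and 41.1% of the others (odds ratio 1.03, 95% interval 0.727 to 1.45, Fisher's exact two-sided p = 0.866). Any annotated gene counted as an overlap, expressed or not, so single genes are not settled. CDKN2A (log2 fold 1.11 here, 0.07 in the authors' table) has such an overlap, and its authors' mean count was 1.59 times that expected. Reads missing from 1 quantification could account for part and stay open, as counts lay more than 4 times apart for 47.9% of these genes against 6.68% of the others. The largest standard error in the authors' table was 0.364, and MMP12, with a mean count of 5.97, had 0.336. Such small errors at low counts go with folds that were shrunk there. Shrinkage as the cause of these differences stays open, as 82.2% had under 100 mean counts, against 24.8%, and the authors' fold was smaller for 77.4%. No biological explanation was tested, since both tables come from the same libraries.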

How the results depend on the processing

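The runs with comparable counts in the authors' table and with the within-group axis as a covariate were chosen after the data were seen, and all other alternatives before. The covariate removes residual variance by construction, so its run decides nothing and is left out of the counts here. The count of 6254 genes stayed within 4757 (offsets for effective length) and 6822 (the authors' table) except as follows. Limma on log2(TPM + 1) gave 3090 genes (1875 higher, 1215 lower), limma on log2(TPM + 0.1) 3212 (1275 lower), and a minimum fold of 1.5, a stricter demand, 1531 (644 higher, 887 lower). For the TPM scales the cause was not tested. Of the 6254 calls, 72.6% were kept with effective length offsets and 31 changed sign, while 44.6% were kept on log2(TPM + 1). For lists, camera with an estimated correlation called 0 (0 higher, 0 lower, 1 at an unadjusted p under 0.05), and fry called 7 higher. Leaving out 1 library gave 2186 to 3719 transcripts (1107 to 1783 higher, 1079 to 2230 lower), with fewer samples. Over 111 named genes, 2206 of 2321 comparisons kept direction and side of the threshold, 84 lost and 14 gained a call, and 17 changed sign. Over 31 lists the counts were 376 of 433, 19, 14 and 24.

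Of the named genes that were called, BSCL2 alone changed sign, at -0.13 in the authors' table, and the other changes of sign were in genes and lists that were not called; the cause was not tested. Among the 6254 calls, 58 changed sign on log2(TPM + 1) and 45 in the authors' table. In the authors' table MT-ND6 was -0.19 and PNPLA2 0.0045. PNPLA2 was 0.0023 with DESeq2 size factors, 0.0011 with thinned counts, 0.080 on log2(TPM + 1) and 0.081 on log2(TPM + 0.1), and FASN was 0.0053 and 0.0055 on those TPM scales. HIST1H1C was -0.052 with library totals and -0.028 with no filter. With library totals the list medians of fatty acid synthesis, fatty acid uptake and glycerophospholipid synthesis were -0.054, -0.031 and -0.061. With no filter they were -0.027, -0.0049 and -0.048, phospholipases 0.044 and antioxidant targets -0.015. Leaving out 1 library gave ranges of -0.11 to 0.062 for PNPLA2, -0.041 to 0.086 for HIST1H1C, -0.0034 to 0.82 for MT-ND6, -0.047 to 0.054 for fatty acid uptake, -0.024 to 0.069 for triacylglycerol synthesis, -0.089 to 0.042 for fatty acid synthesis, -0.047 to 0.029 for glycerophospholipid synthesis, -0.39 to 0.29 for mitochondrially encoded mRNAs and -0.092 to 0.033 for extracellular matrix. With the sign kept, the ranges were -0.20 to -0.051 for FASN, 0.11 to 0.20 for GLB1, -0.12 to -0.029 for lipolysis, -0.21 to -0.036 for phospholipases, -0.11 to -0.0028 for glycolysis, -0.095 to -0.0053 for contractile genes and 0.0023 to 0.077 for antioxidant targets.

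Deviations of same-numbered libraries from their group means correlated at -0.33, 0.014 and -0.31 across genes, which gives no sign of pairing by number. With 3 libraries a group, deviations from the group mean are tied to each other, so these values cannot exclude pairing. With a replicate block, which uses up degrees of freedom, edgeR called 5216 genes and 1433 transcripts (729 higher, 704 lower), the glycerophospholipid median was -0.00020 and the interferon list was called (median 0.25, adjusted p = 0.0205). Thinning to the shallowest library gave 6109 genes. Of the cytokines 10 of 24 had enough counts to test, and on simulated counts the transcript test recovered 19.4% of 2-fold changes, for a cause not tested.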

Other observations

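The gene families and the places of lists on the within-group axis other than that of the mitosis list were chosen after their results were seen, and the other tests before.

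The D-type cyclins, which drive entry into the cell cycle, did not fall with the mitosis genes. CCND1 rose from 651 ± 17.5 to 2506 ± 140 CPM (log2 fold 1.94, n = 3, edgeR adjusted p = 7.5e-10) and CCND2 from 31.1 ± 4.37 to 300.4 ± 25.7 CPM (log2 fold 3.27, edgeR adjusted p = 7.3e-10), while CCND3 stood at -0.043. All 4 tested metallothionein genes fell, with MT1X at -1.21, MT1E at -1.12 and MT2A at -0.58, though these near-identical genes share reads. Of 6 type IV collagen genes, COL4A5 and COL4A6 rose 8.85-fold and 18.7-fold, COL4A1 and COL4A2 fell by 0.53 and 0.42 on the log2 scale and 2 did not pass. All 3 genes of the IGF2 mRNA binding proteins fell, by 2.45 for IGF2BP1, 0.66 for IGF2BP2 and 1.10 for IGF2BP3. These directions held under both other scalings. Of 8 HOXC genes, 3 rose (HOXC10 at 1.81, HOXC11 at 1.91 and HOXC13 at 1.79) and 1 fell, and of 5 HOXD genes 3 rose and 2 did not pass. With library totals 3 HOXC genes rose and 2 fell, and 2 HOXD genes rose. Of 9 HOXA genes, 1 rose and 2 fell (3 with library totals), both tested HOXB genes fell, and of 9 WNT ligand genes 2 rose and 2 fell.

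The libraries of a group differed along an axis that carried 49.6% of the within-group variance, with senescent replicates 1 and 3 at its ends. Across genes, its loadings had a Spearman correlation of -0.305 with GC content, so a GC bias between libraries is a candidate explanation. Transcript length (-0.16) and the share of dividing cells, with the mitosis list at percentile 3.64 of 10000 random lists, stay open. The design names no group within a state, so no biological explanation from it was tested.

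The fall of ribosomal protein genes is argued not to be a length effect, as their median log2 fold less that of the 20 genes nearest in length was -0.35 (95% bootstrap interval -0.46 to -0.26). Less that of the genes nearest in GC content it was -0.40 (-0.43 to -0.35), and summed with 386 processed pseudogenes it was -0.44 (-0.47 to -0.39), which argues against GC content and shared reads. These intervals reflect spread across the 34 genes, whose correlation was estimated at 0.61, and not spread between libraries. The list also sat at percentile 100 of 2000 random lists on the within-group axis, as did oxidative phosphorylation, with histones at 99.8, SASP proteases at 0.1, immediate early genes at 0.55 and lysosome at 0.85. Percentiles give rank and not size. Between senescent replicates 1 and 3, at its ends, ribosomal protein genes differed by a median log2 of 0.061, against a median fold of -0.44. Oxidative phosphorylation differed by 0.055 (median fold -0.20), histones by 0.15 (-0.82) and SASP proteases by -0.25 (0.54). Immediate early genes differed by -0.20 (0.57) and lysosome genes by -0.22 (0.39). Fibroblast markers, at percentile 2.85, differed by -0.24 (-0.31), and mitosis genes, at 3.55, by -0.22 (-2.16). Differences between libraries unrelated to the groups stay open as part of the change in each of these lists. These sizes are below the folds, but for fibroblast markers the difference comes close to the fold. Lower ribosomal protein expression in senescent cells is a hypothesis found and tested on the same data.

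The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes, lists and transcripts alike, 1 of the 10, the real one, gave as many calls. It gave 6254 genes in edgeR against 0 as the highest of the other splits, which had 56 to 760 genes at an unadjusted p under 0.05. It gave 12 lists against 11, and 4740 transcripts against 0, with 553 to 1899 transcripts at an unadjusted p under 0.05 in the other splits. Each other split holds both states on both sides, so the difference between states counts as spread in its tests. Few gene or transcript calls could come from such splits. The states are also mixed unequally there, so the list calls are not those of groups without a difference. The splits therefore do not decide whether chance gave the calls.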
